A study of Drosophila melanogaster with 6 samples.

How the data were processed

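Gene expression was measured in whole wing imaginal discs of larvae of the third instar of Drosophila melanogaster, grown at 25 °C, with 30 discs per sample. Per the labels' protocols, 25 ng of total RNA per sample was amplified and biotin-labelled before hybridization. The 6 arrays form 3 groups of 2. In the GFP RNAi group the act5C-Gal4 driver expresses a hairpin against GFP, which serves as the knockdown control. In the LID RNAi group the same driver expresses a hairpin against lid in larvae that also carry the lid k06801 allele. The wild type group is titled as wild type and has no RNAi in the RNAi field of its labels, but its genetic background field names w1118 together with the act5C-Gal4 driver. The samples were grouped by title. A control probe set, described among the results for a closer look, read at background on both wild type arrays and high on the 4 RNAi arrays, which separates the arrays as the titles do. Knockdown and mutant allele come together in the LID RNAi group, so no comparison separates them, and the strains also differ in background.

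The deposited table holds log2 values per probe set, made with RMA per the submitters' processing notes, with no version given. The values span about the same range on each array, and the array medians lie between 6.31 and 6.43. No further scaling was applied for the reported values. Of 18952 probe sets, 183 are controls of the manufacturer and 18769 were tested. A single gene symbol was paired with 13647 of the tested probe sets, several symbols with 402 and none with 4720. The 13647 stand for 11982 genes, and the symbols of 13544 of them were found in the gene table of the assembly Release 6 plus ISO1 MT. That table was used for names and for the order of genes only. A gene with several probe sets was represented by the one with the highest mean over all arrays. For the tests on neighbouring genes and on other probe sets, a gene counted as differing from both controls if any of its probe sets did. Background was taken from 27 probe sets for Bacillus subtilis transcripts, with a median of 3.27 and a 95% point of 4.82, a choice made after seeing the data. Where the lower group mean of a gene lies at or below 4.82, its change is a lower bound and its rank by size is not resolved, and where both lie there the levels are not told from background.

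A linear model with 1 mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, which leaves 3 residual degrees of freedom, to which the moderated variance added a prior of 1.77. Contrasts were LID RNAi against GFP RNAi, LID RNAi against wild type, GFP RNAi against wild type and LID RNAi against the mean of both controls. All adjusted p-values of genes are Benjamini-Hochberg values from limma over all 18769 probe sets, with a threshold of 0.05, and tests were two-sided. Changes are differences of group means in log2 with their standard error (SE) from the fit, and n = 2 arrays per group throughout. The labels do not say whether the 2 arrays of a group come from separate dissections. If they do not, SE and p-values leave out the spread between dissections. The number of arrays limits the precision. With groups of 2, other splits of the samples were not counted.

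Before the data were examined, the tests, the alternatives, the rule for the genes named and 34 lists of genes were fixed. Of these lists, 32 had at least 5 measured members and were tested with camera in limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. The histone list (3 measured) and the list of transgene and strain markers (2 measured) were counted but not tested. The genes named are lid, up to 12 genes per direction with the largest change between LID RNAi and GFP RNAi and up to 5 per direction for the other pairs, taken from genes past the threshold whose arrays do not overlap between the groups. Up to 10 genes per direction are named for a change against both controls, and up to 4 members past the threshold for each list. Where no member of a list passed, the member with the largest change is named for LID RNAi against GFP RNAi, and for the other pairs such lists are summarised by their counts. A few further members past the threshold are named beyond these 4, chosen after their values were seen.

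The fit was tested on simulated data for 18769 probe sets, 200 of them changed in the LID RNAi group. For LID RNAi against GFP RNAi it recovered 14.9% of the 1.5-fold changes, 49.3% of the 2-fold changes and 77.3% of the 4-fold changes, with 5 false calls. For LID RNAi against wild type the shares were 17.9%, 52.2% and 78.8%, with 5 false calls. A simulated list shifted by 0.5 in log2 was called by camera, and of the 32 lists tested 0 others were called. Genes were drawn independently of each other in this simulation. It therefore does not show the rate of false calls for correlated lists, such as the haemocyte markers with an estimated correlation of 0.499.

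Alternatives changed 1 choice at a time, except that the eBayes alternative set the trend and the robust hyperparameters together. They were cyclic loess, quantile normalization or median centring of the arrays, a filter on low levels, 1 probe set per gene, eBayes with a trend and robust hyperparameters, only the groups compared, the replicate number as a block, stricter thresholds and each array left out in turn. For lists they were an estimated correlation, fry, the mean of a gene's probe sets, the filter, the block and each array left out. Scaling alternatives for the lists were chosen after seeing the data. A pseudocount did not apply, since the values are log2. The block is treated as an alternative because the labels do not say that a replicate number marks a shared batch.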

Results

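Expression in whole wing imaginal discs was profiled on 6 arrays, with 2 arrays each for discs with lid knockdown in a lid mutant background (LID RNAi), discs with the control hairpin (GFP RNAi) and wild type discs. Array medians were 6.35 and 6.39 in GFP RNAi, 6.36 and 6.31 in LID RNAi and 6.43 and 6.38 in wild type, on the log2 scale. Replicate arrays correlated across probe sets with r = 0.995 in GFP RNAi, 0.995 in wild type and 0.990 in LID RNAi, where probe sets are not independent replicates. LID RNAi replicate 1 correlated with GFP RNAi replicate 1 at r = 0.993, above its own replicate. LID RNAi replicate 2 stood apart from the others. Its signal at the 3′ end exceeded that at the 5′ end by 3.54 for GAPDH, against 2.67 to 3.17 on the other 5 arrays, and by 1.45 for Act5C, against 1.09 to 1.34.

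The first question is whether the targeted transcript was lowered. The gene lid, named Kdm5 in current tables, encodes a demethylase of trimethylated histone H3 lysine 4. Its level was 8.20 ± 0.23 (SD, n = 2) in LID RNAi, against 10.39 ± 0.10 (SD, n = 2) in GFP RNAi and 10.37 ± 0.06 (SD, n = 2) in wild type. The single arrays read 8.36 and 8.04 in LID RNAi, 10.32 and 10.45 in GFP RNAi and 10.42 and 10.33 in wild type. Kdm5 fell by 2.19 ± 0.13 (SE) against GFP RNAi, to 22.0% of that control (limma adjusted p = 0.0309), and fell by 2.17 against wild type (adjusted p = 0.00877). Between GFP RNAi and wild type it differed by 0.01 (adjusted p = 0.987). The call against GFP RNAi ended when any 1 array was left out, with a change between -2.35 and -2.02 and adjusted p between 0.0573 and 0.220. Against wild type the call ended without wild type replicate 1 (adjusted p = 0.0805) and without wild type replicate 2 (adjusted p = 0.0709).

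**Figure D1:**
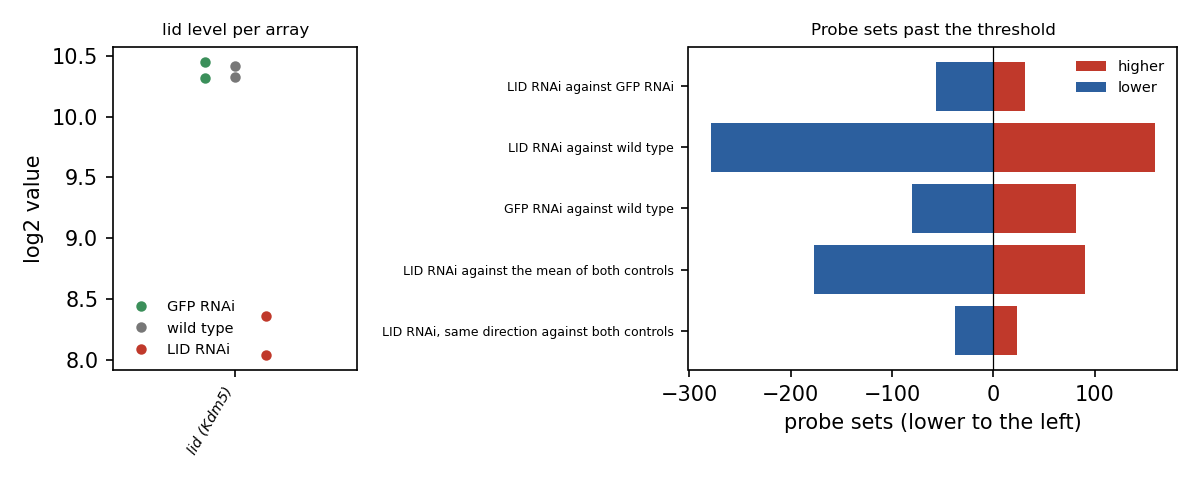
Left, lid level in log2, 1 point per array, coloured by group; right, the number of probe sets higher or lower at an adjusted p under 0.05 in each comparison. The 2 LID RNAi arrays lie at 8.36 and 8.04, below all 4 control arrays.

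LID RNAi against GFP RNAi asks what differs in discs that carry the same driver. The genes del and cuff, which encode partners in a complex that drives piRNA cluster transcription, stood at -1.84 ± 0.14 and -1.72 ± 0.07 (SE, n = 2 arrays per group) in log2. The detoxification genes Cyp6a13 and Cyp6d2, which encode cytochromes P450, fell by 2.08 and 1.89, where Cyp6d2 stood at 7.61 in LID RNAi and 7.82 in wild type, against 9.50 in GFP RNAi. The translation initiation factor gene eIF4E3 rose by 3.19 ± 0.30 and the salivary gland gene ng1 by 2.28 ± 0.15. Markers of haemocytes, the blood cells of the larva, were higher as a set, with a median change of 0.62 (camera adjusted p = 0.000155, and adjusted p = 0.897 with an estimated correlation).

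In total 31 probe sets rose and 57 fell, which stand for 24 and 42 genes, and 13 of the 88 had no gene name. At an unadjusted p under 0.05 in limma, 2330 of 18769 probe sets differed, a number that includes those expected by chance at this threshold. Without GFP RNAi replicate 1, GFP RNAi replicate 2 or LID RNAi replicate 2, limma called 0 probe sets (1773, 1644 and 2197 at an unadjusted p under 0.05). It called 3 without either wild type array and 6 without LID RNAi replicate 1, where the lone array of a group is assumed to vary like the other groups.

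The largest measured rise among named genes was that of mthl8, a gene of the methuselah-like receptor family, at 6.12 ± 0.29 (SE, adjusted p = 0.0138). Its level was 9.21 in LID RNAi and 8.92 in wild type, against 3.09 in GFP RNAi, so that the GFP RNAi arrays were the ones apart. CG13526 rose by 4.48, CG6434 by 3.66, CG14692 by 2.99, CG10384 by 2.45 and CG43103 by 2.38. The genes l(2)34Fc, Spn47C, CG30016 and CG14879 rose by 2.05, 1.92, 1.79 and 1.57. The largest fall among named genes was that of the ionotropic receptor gene Ir76a, at -3.84 ± 0.09 (SE, adjusted p = 0.00287). Ir76a stood at 9.38 in GFP RNAi, against 5.55 in LID RNAi and 5.64 in wild type. Jhbp12 fell by 2.35, the transporter gene ine by 2.24, Arc2 by 2.21, CG31676 by 2.07, rdog by 1.96 and the serpin gene Spn42De by 1.85, and CG3860 fell from a level of 9.86 to 7.86. Wild type levels lay nearer to LID RNAi than to GFP RNAi for ine (5.68, against 5.32 and 7.55), CG31676 (6.15, against 6.49 and 8.56), CG3860 (7.81) and l(2)34Fc (12.35, against 11.66 and 9.60). They lay between both groups for Cyp6a13 (6.51), Arc2 (9.26) and rdog (7.99), by a smaller margin nearer to LID RNAi. Adjusted p-values of these genes, apart from Cyp6a13, whose value follows below, lay between 0.00287 and 0.0490. The lower level was within background, up to 4.82, for mthl8, CG13526, CG6434, CG10384 and ng1, so that their changes are lower bounds and their order by size is not resolved.

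Among 28 measured genes of small RNA pathways 2 fell, del and cuff (adjusted p = 0.0338 and 0.00878), and 26 did not pass. Adjusted over the list alone, 3 rose and 4 fell. Of 152 glutathione transferases and cytochromes P450, 2 fell, Cyp6a13 and Cyp6d2 (adjusted p = 0.0496 and 0.0367), and adjusted over the list alone 1 rose and 8 fell. Among 25 salivary gland markers ng1 rose (2 rose adjusted over the list alone), and among 25 gut markers the lysozyme gene LysX fell by 1.62, with both levels within background (1 fell adjusted over the list alone). The medians of these lists were -0.01, -0.03, 0.08 and 0.05, and none passed camera. On the single LID RNAi arrays, against the mean of the 4 control arrays, salivary gland markers had medians of -0.09 and 0.62 and gut markers 0.41 and -0.51, for replicates 1 and 2.

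Camera called 4 lists without a member past the threshold over all genes, and each lost the call with an estimated correlation. Haemocyte markers were higher in 18 of 19 members, among which lz, a regulator of crystal cells, differed by 1.72 ± 0.27 (SE, adjusted p = 0.111) from a GFP RNAi level within background. Mitochondrial ribosomal proteins were higher in 60 of 71 members with a median of 0.08 and 0.33 for mRpL27 (camera adjusted p = 0.000155, and adjusted p = 0.897 with an estimated correlation). Genes of oxidative phosphorylation had a median of 0.06 with 56 of 75 above 0 and -0.89 for COX7AL2 (camera adjusted p = 0.0346, and adjusted p = 0.897 with an estimated correlation). Muscle and myoblast markers had a median of 0.29 with 16 of 21 above 0 and 1.07 for Mlc1 (camera adjusted p = 0.0346, and adjusted p = 0.897 with an estimated correlation). A single haemocyte marker rose adjusted over the list alone, and no member of the others passed. Without LID RNAi replicate 2, the array with the wider gap between transcript ends, camera no longer called mitochondrial ribosomal proteins (adjusted p = 0.113) or oxidative phosphorylation (adjusted p = 0.759). The latter call also ended without GFP RNAi replicate 1 or 2 (adjusted p = 0.102 and 0.0615), and that of muscle markers without LID RNAi replicate 1 or GFP RNAi replicate 2 (adjusted p = 0.252 and 0.0816). Haemocyte markers passed without it (adjusted p = 0.00126) and without each other array, the highest adjusted p being 0.0300 without GFP RNAi replicate 1.

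**Figure D2:**
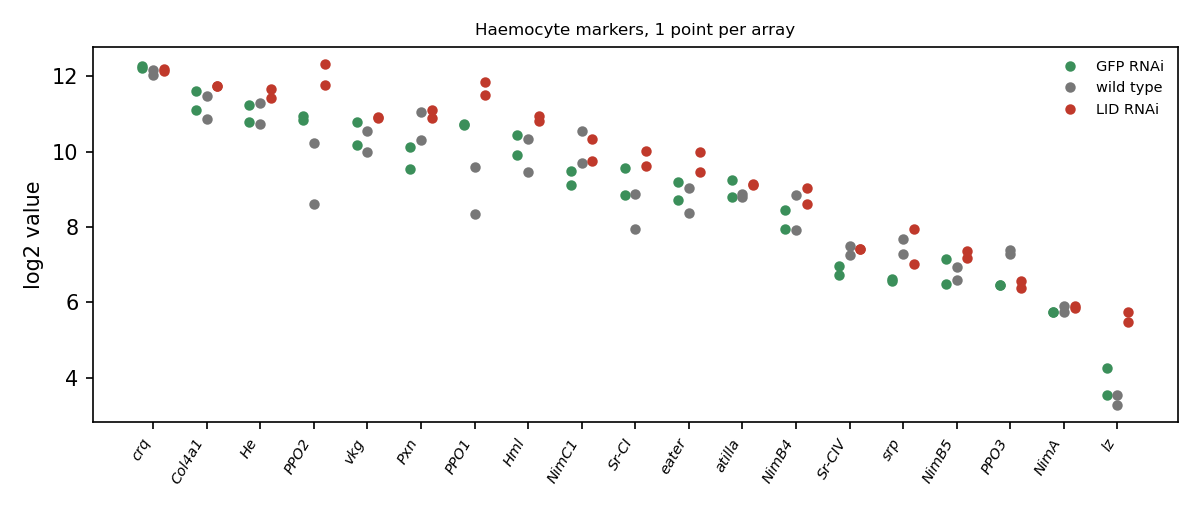
Log2 level of the 19 haemocyte markers, ordered by their mean, 1 point per array and coloured by group. PPO2 reads 12.33 and 11.78 in LID RNAi and 8.62 to 10.94 on the 4 control arrays, while crq reads 12.05 to 12.26 on all 6.

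Chromatin and patterning lists had no member past the threshold. The largest differences were -0.40 for Hcf among 24 genes of H3K4 methylation, 0.32 for Pcl among 17 Polycomb group genes, 0.21 for Scr among 5 homeotic genes and 0.81 for Lim1 among 48 genes of wing disc patterning. In growth and stress lists they were 0.86 for Ocho (Notch pathway, 19 genes), 0.29 for wcd (Myc targets, 28), 1.57 for RpS19b (cytosolic ribosomal proteins, 41), -0.73 for Gclc (antioxidant genes, 19) and -0.68 for Pdp1 (circadian clock, 11). They were -0.43 for sub (cell cycle, 34), -1.25 for Corp (apoptosis and p53, 14), -0.86 for Timp (wound response, 19), -0.49 for REPTOR (growth signalling, 23) and 1.17 for Hr4 (ecdysone response, 23). Values were 2.10 for Lcp65Ag3 (cuticle and chitin proteins, 128), 1.76 for Drsl5 (immune response, 31), -2.35 for Hsp68 (heat shock, 15) and -1.70 for aub (germline and testis genes, 44). Among the remaining lists they were -0.17 for dsx (male dosage compensation, 9), 0.55 for FASN1 (fat body, 15), 0.85 for rib (trachea, 17), 0.70 for nrv3 (nervous system and glia, 26) and -0.49 for Rpt3R (proteasome, 41). The eye and leg disc list (23) again had lz at 1.72, the histone list (3) had cid at 0.42 and the strain markers (2) had y at 0.43. A single gene each rose, adjusted over the list alone, among Notch, cytosolic ribosomal, eye and leg disc, histone and strain marker genes, and 1 antioxidant, 2 apoptosis and 3 cuticle genes fell. In the remaining lists no gene passed adjusted over the list alone. Median, mean and camera differed in sign for the H3K4 methylation, homeotic, Notch, cytosolic ribosomal, ecdysone, immune, fat body, eye and leg disc and gut lists, none of them past the threshold.

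LID RNAi against wild type sets the knockdown discs beside discs titled as wild type, for which the labels give no RNAi. The named genes with the largest measured rises, t, CG30356, CG13032, CG43103 and CG17778, also rose in GFP RNAi against wild type. The gene t, which encodes the tan hydrolase of cuticle pigmentation, rose by 5.99 ± 0.15 (SE, adjusted p = 0.00179) and stood at 9.55 in LID RNAi, 8.52 in GFP RNAi and 3.56 in wild type. The piRNA genes del and cuff fell by 1.82 and 1.41, and tej by 2.13, which fell by 1.53 in GFP RNAi against wild type as well. Haemocyte markers were higher as a set, with a median of 0.51 (camera adjusted p = 0.00456, and adjusted p = 0.976 with an estimated correlation).

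In total 160 probe sets rose and 279 fell, which stand for 116 and 210 genes, and 63 of the 439 had no gene name. Without wild type replicate 1 the count was 24 and without wild type replicate 2 it was 27. It was 99 without either GFP RNAi array, 128 without LID RNAi replicate 2 and 324 without LID RNAi replicate 1. CG30356 rose by 5.41 ± 0.07 (SE, adjusted p = 0.000316), CG13032 by 4.90, CG43103 by 4.76 and CG17778 by 4.49. Among the falls, CG5282 fell by 4.35, the odorant-binding protein gene Obp56a by 4.23, CG31809 by 3.95, CG34247 by 3.86 and lncRNA:CR32368 by 3.58. The lower level of t, CG13032, CG5282 and CG31809 was within background, so that these changes are lower bounds without a resolved order.

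Of the 28 genes of small RNA pathways 1 rose, nxf2 by 0.63, and 4 fell, namely tej, del, cuff and qin, the last by 0.63, while 6 rose and 5 fell adjusted over the list alone. Glutathione transferases and cytochromes P450 split, with Cyp9c1, GstD9 and GstD3 higher by 2.01, 1.35 and 0.74, and Cyp4e2, Cyp6a20, Cyp313a2 and GstZ1 at -2.21, -2.06, -1.39 and -1.18 (10 rose and 11 fell adjusted over the list alone). Cuticle and chitin genes split too, with Cpr49Ah and obst-E higher by 2.33 and 1.44 and Cpr47Ee, TwdlW and Cpr76Bc at -3.30, -1.10 and -0.73 (3 rose and 4 fell adjusted over the list alone). In single lists Prx6c fell by 3.21 (antioxidant genes), skl by 1.38 (apoptosis), ase by 1.08 (wing disc patterning), SdhB by 0.53 (oxidative phosphorylation) and LysX from a level of 4.14 to 3.14 (gut). PGRP-LF rose by 1.23 (immune response), ng1 by 2.71 (salivary gland) and sls by 1.11 (muscle). Both levels were within background for skl, LysX and Cpr76Bc, and the lower level was for Prx6c, Cyp313a2, Cpr47Ee, qin, lz and ng1, whose changes are lower bounds. No gene passed adjusted over the list alone for oxidative phosphorylation, while 2 fell each for apoptosis and patterning, 1 rose and 1 fell for muscle, and 1 passed for each of the other lists.

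Haemocyte markers were the 1 list past the threshold of camera, higher in 17 of 19 members. Within the list lz rose by 2.20 ± 0.27 (SE, adjusted p = 0.0346), which is the 1 gene past the threshold in the eye and leg disc list as well (1 rose adjusted over the list alone), and PPO3 fell by 0.85 (adjusted p = 0.0292), while 3 rose and 1 fell adjusted over the list alone. The camera call ended without wild type replicate 2 (adjusted p = 0.0876) and without LID RNAi replicate 1 (adjusted p = 0.0865). In the lists not named here no member passed, and 1 circadian gene and 2 nervous system genes fell adjusted over the list alone. Median, mean and camera differed in sign for 15 lists, none past the threshold.

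GFP RNAi against wild type compares the groups without a knockdown of lid. A field of the labels names the driver for both groups, but a control probe set read 11.91 and 11.85 in GFP RNAi against 3.07 and 2.96, within background, in wild type (AFFX-Dm-K01486-1_at, limma adjusted p = 0.00127). Large differences were present here as well. CG30356 rose by 5.16 ± 0.07 (SE, adjusted p = 0.000393), t by 4.96, CG13032 by 4.65, Reepl1 by 3.97 and CG17778 by 3.89. The gene mthl8 fell by 5.82 ± 0.29 (SE, adjusted p = 0.00827), CG30098 by 4.78, CG5282 by 4.48, the peroxiredoxin gene Prx6c by 3.04 and lncRNA:CR32368 by 2.97. Changes of t, CG13032, mthl8, CG30098, CG5282, Prx6c and Cpr47Ee are lower bounds, since their lower level was within background, as were both levels of Cpr76Bc.

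In total 82 probe sets rose and 80 fell, which stand for 64 and 56 genes. The count was 4 without either GFP RNAi array, 17 without wild type replicate 1, 16 without wild type replicate 2 and 90 without either LID RNAi array. Of the detoxification genes 5 rose and 1 fell, with Cyp9c1, Cyp6t1, Cyp6d2, GstE1 and GstE5 higher by 2.21, 1.74, 1.67, 1.26 and 1.15 and Cyp6a20 at -2.08, and adjusted over the list alone 11 rose and 5 fell. Of the cuticle genes Cpr47Eb rose by 1.37, and Cpr47Ee, Cpr67Fb and Cpr76Bc stood at -2.94, -1.24 and -0.92 (4 rose and 4 fell adjusted over the list alone). PGRP-LF rose by 1.06, tej fell by 1.53 and PPO3 fell by 0.87, and each was the 1 gene of its list adjusted over the list alone. Among antioxidant genes 1 rose and 1 fell adjusted over the list alone.

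Mitochondrial ribosomal proteins were the 1 list past the threshold of camera, lower in this comparison with a median of -0.08 and 10 of 71 members above 0 (adjusted p = 0.00178, and adjusted p = 0.944 with an estimated correlation). The call ended without GFP RNAi replicate 1 (adjusted p = 0.166) and without wild type replicate 1 (adjusted p = 0.0761). The GFP RNAi arrays lay lowest for this list, with medians of -0.09 and -0.02 relative to the mean of all arrays. The LID RNAi arrays stood at 0.01 and 0.05 and the wild type arrays at 0.04 and 0.02. Of the other lists without a passing member, apoptosis had 1 gene higher and 2 lower and nervous system and strain markers 1 lower each adjusted over the list alone, and camera called none. Median, mean and camera differed in sign for 10 lists, none past the threshold.

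Genes that differ from both controls in the same direction are those that neither control strain alone sets apart. CG13526, CG14692, CG6434, CG43103 and eIF4E3 rose by 4.36, 3.73, 3.69, 3.57 and 3.34 against the mean of both controls. Spn47C, ng1, CG10384, mthl6 and CG14879 rose by 2.57, 2.49, 2.45, 1.97 and 1.93. Beside Kdm5, the genes Jhbp12, del, CG30195, CG14314 and Spn42De fell by 2.73, 1.83, 1.76, 1.76 and 1.72. CG18537, St3, grass, which encodes a serine protease of Toll signalling, and cuff fell by 1.64, 1.61, 1.58 and 1.57. The values of CG14692 and St3 are each those of 1 probe set, and their other probe set moved less, with a rise of 0.99 and a fall of 0.26. For CG13526, CG14692, CG6434, ng1, CG10384 and mthl6 a control level was within background, so that their rises are lower bounds without a resolved order.

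**Figure D3:**
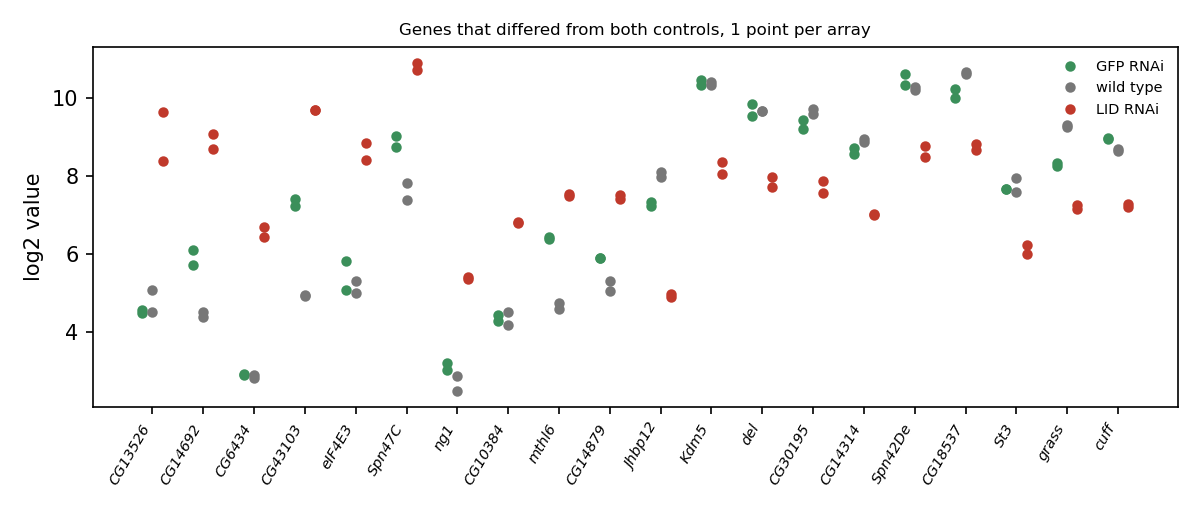
Log2 level of the 20 genes named for a difference from both controls, 1 point per array, with GFP RNAi, wild type and LID RNAi side by side. For CG6434 the LID RNAi arrays read 6.69 and 6.44 and the 4 control arrays 2.81 to 2.92.

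In all, 23 probe sets rose and 38 fell against both controls, and 9 of the 61 had no gene name. Both comparisons use the same LID RNAi arrays, which are too few to split, so that some overlap is built in. Against the mean of both controls 91 probe sets rose and 177 fell, and haemocyte markers were the 1 list past camera (adjusted p = 0.000303, and adjusted p = 0.960 with an estimated correlation). LID RNAi and GFP RNAi shared 50 higher and 62 lower probe sets against wild type. These comparisons share the wild type arrays, so that some overlap is built in. Leaving out any 1 array left 0 to 3 of the 61 and 5 to 81 probe sets against the mean of both controls, with 0 and 19 without LID RNAi replicate 2. Such fits leave a lone array in 1 group, so their counts do not show which changes persist.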

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

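A manufacturer's control probe set that belongs to no comparison above differed between the groups. AFFX-Dm-K01486-1_at read 11.91 and 11.85 in GFP RNAi, 11.87 and 11.32 in LID RNAi and 3.07 and 2.96 in wild type. It was higher by at least 8.58 in LID RNAi (limma adjusted p = 0.000923) and at least 8.86 in GFP RNAi (adjusted p = 0.00127) than in wild type, where the level lies within that of background probe sets, up to 4.82. The tables used here do not name its transcript, but the accession in its name is, as background knowledge, that of the yeast GAL4 gene. The 4 arrays with a high value are those whose titles name an RNAi. The genetic background field names the act5C-Gal4 driver for the wild type samples too. With GAL4 as its target, the wild type arrays showed no driver transcript above background, against that field. Their titles say nothing of a driver.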

How the results depend on the processing

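Of the alternatives, the scalings of the gene lists were chosen after seeing the data. The 3 scalings (cyclic loess, quantile normalization, median centring) and 1 probe set per gene kept every count of probe sets within 1.5 times, and cyclic loess kept 79 of the 88 probe sets called between LID RNAi and GFP RNAi. Median centring moved the split against wild type from 160 higher and 279 lower to 210 and 240. In the order LID RNAi against GFP RNAi, against wild type, GFP RNAi against wild type, LID RNAi against both controls' mean and both controls in the same direction, the main counts were 88, 439, 162, 268 and 61. They became 281, 816, 328, 657 and 162 with a trend and robust eBayes, and 9, 64, 26, 26 and 6 at an adjusted p under 0.01. With only probe sets above the median level they were 247, 749, 602 and 162, the third comparison staying within 1.5 times at 243. A fold of at least 2 left 249 against wild type and 130 against the mean of both controls. With only the groups compared, counts were 3, 99, 90 and 1 (the mean of both controls needs all groups), where fewer arrays estimate the spread. Leaving out 1 array gave 0 to 6, 24 to 324, 4 to 90, 5 to 81 and 0 to 3, with fewer residual degrees of freedom. Of 107 gene results past the threshold that were followed, most lost the call in at least 1 such fit. None changed direction, which was fixed in advance for genes whose arrays do not overlap between the groups.

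With the replicate number as a replicate block, counts were 12, 200, 41, 41 and 10, and the call of lid against GFP RNAi ended, with a change of -2.19 and an adjusted p of 0.0820. Deviations of same-numbered arrays correlated across probe sets at 0.298, 0.0646 and 0.223 for the 3 pairs of groups. These values are positive and do not exclude a batch shared by number. The numbers were not taken to pair the arrays because the labels do not say so. Without 1 array the change of lid ranged from -2.35 to -2.02. Gene lists past the threshold numbered 4, 1 and 1 in the 3 pairs of groups. They became 0, 0 and 0 with an estimated correlation, and 0, 1 and 0 with fry, whose 1 list was apoptosis and p53 (adjusted p = 0.0335), not the haemocyte markers (adjusted p = 0.631). The filter gave 7 lists for LID RNAi against GFP RNAi and 2 for GFP RNAi against wild type, and leaving out 1 array gave 2 to 5, 0 to 3 and 0 to 2. The scalings of the lists gave 3, 1 and 1 each. Oxidative phosphorylation lost its call with cyclic loess (adjusted p = 0.139) and quantile normalization (adjusted p = 0.148), and muscle markers with median centring (adjusted p = 0.0556) and with the mean of a gene's probe sets (adjusted p = 0.0587).

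Differences that had not passed changed sign when 1 array was left out. Ranges were -0.21 to 2.55 for Hr4, -1.27 to 4.78 for Drsl5 and -0.10 to 1.80 for rib against GFP RNAi, and -0.30 to 0.051 for Dfd and -1.19 to 0.12 for Kaz-m1 between LID RNAi and wild type. Between GFP RNAi and wild type they were -3.86 to 0.14 for Hr3 and -0.054 to 0.081 for Kdm5. The cause of the changes with eBayes, the block and the list tests was not tested. The pseudocount was not run, since the values are log2.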

Other observations

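Of the tests on the haemocyte markers, those on carry-over of other tissues, with its reading per array, and on attached haemocytes were chosen after the result was seen, and the rule of the test on neighbouring genes was tightened after its value was seen. The haemocyte markers differed from the mean of both controls by unequal amounts. The crystal cell genes PPO1 and PPO2, which encode prophenoloxidases, stood 1.83 and 1.90 above it, and lz, which specifies crystal cells, at least 1.96 above it, from control levels within background. Genes of plasmatocytes, the phagocytic blood cells, stood at -0.02 for crq, 0.09 for NimA, 0.31 for NimC1, 0.75 for Pxn, 0.85 for Hml, 0.89 for eater and 1.02 for Sr-CI, and He stood at 0.53. The lamellocyte genes PPO3 and atilla stood at -0.42 and 0.20. The levels of PPO2 were 12.33 and 11.78 in LID RNAi, 10.83 and 10.94 in GFP RNAi and 10.23 and 8.62 in wild type. Those of Pxn were 11.11 and 10.90 in LID RNAi, 9.54 and 10.13 in GFP RNAi and 11.06 and 10.30 in wild type. PPO1 and PPO2 were thus lower in wild type than in GFP RNAi and Pxn higher, which the mean of both controls hides. Against GFP RNAi alone Pxn rose about as much as PPO2, while NimC1, Hml, eater and Sr-CI rose less than either PPO gene. The grouping of the members by cell type was chosen after their values were seen, and the difference between cell types was not tested.

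The haemocyte markers were weighed first. Lower RNA quality on LID RNAi replicate 2 is argued against as their cause, since on LID RNAi replicate 1 alone they had a median of 0.64 above the 4 control arrays, where matched random lists gave -0.12 to 0.11. Carry-over of several larval tissues cannot be told apart: over both arrays the medians of fat body, gut, tracheal, salivary gland and nervous system markers reached 0.19 and that of muscle and myoblast markers 0.27, against 0.52 for haemocyte markers, which met the bound set for the first 5, but this mean hides single arrays, with 0.62 for salivary gland markers on replicate 2 and 0.41 for gut markers on replicate 1. More attached haemocytes may account for the set, but 61.5% of the markers with a mean level above the median of all genes (8 of 13) were higher on both LID RNAi arrays than on each control array, between the bounds set for and against it. Random lists leave out the correlation between markers, estimated at 0.499. Relative to the mean of all arrays, the medians were -0.39 and 0.07 in GFP RNAi and 0.006 and -0.46 in wild type. They were 0.49 and 0.24 in LID RNAi, so that the arrays of each control group differed widely too. Chance differences between dissections and an effect of lid loss on blood cells therefore stay open. Strain background, which the design does not separate from lid loss, stays open for these markers too.

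For the genes that differ from both controls, strain background within the 200 measured genes nearest to lid is argued against as a main source. Among these 200, in the gene order of Release 6 plus ISO1 MT, lay 1 of 48 genes with any probe set past the threshold (lid left out). This 1 gene was KFase, where 0.807 were expected (one-sided Fisher's exact p = 0.558), with an upper 95% bound of 11.1%. Linked background farther along the chromosome was not covered and stays open. Blocks of strain-specific sequence elsewhere in the genome cannot be told apart: 2 of 49 genes with any probe set past the threshold had another such gene among the 5 nearest on either side, at the median of 2 of random sets, which met the bound set beforehand, but the count's upper bound of 7.22 exceeds the 6 at the 95% point of the random sets. Sequence variants under single probe sets are a candidate explanation for part of the genes. In the 5 of 49 genes with other probe sets, those moved in the same direction by 0.159 of the change of the called ones (medians of 0.26 and 1.64). These medians come from different genes, St3 and Cadps, so their ratio is not one within a gene. Within genes the others moved by 0.24 against 0.84 for alpha-Man-Ia, 0.99 against 3.73 for CG14692 and 0.26 against 1.61 for St3. They moved by 0.095 against 2.34 for mod(mdg4) and by 1.81 against 1.64 for Cadps. The called probe set with the largest change stood for each gene, so smaller changes of the others are partly built in. Probe sets of other transcript forms, as for mod(mdg4) with 21 others, would give a low value too, so the ratio does not decide. An effect of lid loss stays open beside these, since the design does not separate it from strain background. Lower RNA quality on LID RNAi replicate 2 was not tested as a source of these genes and stays open too. Its gap between transcript ends was 3.54 for GAPDH, against 2.77 on replicate 1.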
